A study of Mus musculus with 2 samples.

How the data were processed

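The study profiled binding of STAT5, the transcription factor that cytokine receptors such as the IL7 receptor activate, by chromatin immunoprecipitation and sequencing (ChIP-seq). Per the labels, the cells came from the lymph nodes of a mouse with B cell progenitor leukemia that carried a constitutively active Stat5b transgene and 1 mutant copy of Blnk, an adaptor of pre-B cell receptor signalling. Per the labels' protocols, the cells were given 10 ng/mL IL7 for 30 minutes, fixed in 1% formaldehyde for 10 minutes and sonicated to fragments of about 200 bp. The samples were 1 STAT5 ChIP library and 1 input library, that is, sonicated chromatin without immunoprecipitation. There were no replicates, so no spread between animals or libraries could be estimated.

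The deposited values were peak positions: the start and end of each interval on mouse build mm10, in bp, with a name and no other measurement. The submitters' processing notes name BWA 0.7.4, Picard, MACS2 and mm10, without saying what each was used for. The alignment settings, read filters, peak-calling threshold and use of the input library are not given in the sources used here. Read depth is unknown, and no height, fold enrichment or significance of a peak was used. The names were numbered from 1 to 5908 without gaps in order of position, while the lines stood in another order. Earlier lines held wider intervals (Spearman's rho -0.649 across peaks, median width 425 bp in the first 20% of the lines and 229 bp in the last 20%). The key of that order is not given in the sources used here. A peak's place in the deposited order was used to choose which peaks to name, in an alternative setting, and in shares given for chromosome X and for 2 gene lists. With its key unknown, it is not a measure of binding.

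Positions are given from 1, as a genome browser shows them. Genes came from an NCBI RefSeq table of assembly GRCm38.p6, which has the coordinates of mm10. It gave the start, end and type of each gene, without strand, exons or sequence. Genes with a start under 3000000 bp on any chromosome but Y, 340 in all, were taken to carry positions on unplaced or alternate sequences. They were left out. Of the 49603 genes kept, 21779 were protein-coding. Whether a peak lay in an exon, an intron, an untranslated region or a promoter was not determined, nor which end of a gene is its transcription start. The classes planned before the data were examined needed these, and were replaced by 4 classes of the peak midpoint, in this order of precedence: within 1 kb of either end of a protein-coding gene, inside a protein-coding gene, inside another annotated gene (a noncoding gene, a pseudogene or an antigen receptor segment), and intergenic. The planned searches with 25 motifs (content, position, rank and co-occurrence) and every GC-matched comparison needed the genome sequence and were not run. No column of values was left unused.

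Of the 5908 peaks, 5901 lay on the assembled chromosomes and entered the tests. The usable length of a chromosome was taken from the start of its first to the end of its last protein-coding gene. Chromosomes were compared with 10000 random assignments of the peaks in proportion to that length. These assignments, and the placements used for the classes, treat peaks as independent, although peaks lie in groups, so their p-values are too small. Classes and distances between peaks were compared with 1000 random placements on the same chromosomes. Densest regions were found as groups of at least 4 peaks within 50 kb. For 20 gene lists written before the data were examined, a gene was counted when a peak midpoint lay inside it or within 20 kb of either end. The count was compared with 10000 random lists in which each member was replaced by 1 of the 200 protein-coding genes nearest to it in length. These draws treat genes as independent, although neighbours can share a peak. The lists overlap in part. Permutation tests of single chromosomes, classes, lists and gene families were two-sided. They were adjusted by the Benjamini-Hochberg method within each of these sets, with 0.05 as the threshold. The test of the chromosomes as a set counted only deviations at least as large as that observed. It was not adjusted, nor were the permutation tests of peak distances, dense regions, density correlations and peak widths. All these p-values describe positions within this 1 peak list, not variation between animals. Shares carry exact (Clopper-Pearson) 95% intervals and peak counts exact Poisson intervals, which cover counting error only. Pairs of lists were compared by Fisher's exact test, with genes in both lists left out where there were any. B lineage factor genes were also compared with housekeeping and ribosomal protein genes given gene length, by an exact conditional test in which each gene had the odds of a peak of the 200 genes nearest to it in length, adjusted over 6 tests (flanks of 5, 20 and 50 kb).

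The gene list test was tested on simulated peaks around 21779 genes, with 25 genes per list and 60% of the members of 1 planted list per run given a peak. It called 19 of 20 planted lists and 2 of 380 lists with nothing planted. The simulated peaks were placed independently and the lists were drawn at random. These rates therefore do not cover grouped peaks or lists whose members are neighbours, as in the real data.

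Genes were named by a rule fixed before the data were examined, with place in the deposited order standing in for the score and the nearest gene end for the nearest transcription start: the gene nearest to each of the first 20 peaks, up to 4 members of each list by their earliest peak, 20 fixed genes whatever their values, and the genes at the 5 densest regions. A few genes that this rule takes are not reported here. The other genes, the gene families, the antigen receptor loci and the list pairs compared were chosen after their values were seen, as was the comparison of STAT5 target peaks with those of B lineage factors.

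The alternatives planned and run were peaks closer than 200 bp merged, assembled chromosomes only, peaks closer than 5 kb counted as 1 for chromosomes, placement that keeps the class of each peak, a 20 kb window, any overlap of 1 bp in place of the midpoint, protein-coding genes only, flanks of 5 kb or 50 kb, and random lists unmatched or matched also on the number of genes within 100 kb. Those chosen after the data were examined were the 2931 widest peaks, gene ends within 5 kb and the gene with the end nearest to a peak (each in place of a setting that needed a score or a transcription start), the first 2954 peaks of the deposited order, leaving out 44 doubtful peaks, peaks closer than 5 kb counted as 1 for dense regions, chromosomes by gene number, autosomes only, and matching among named genes only. Doubtful peaks were those outside the assembled chromosomes or the gene span, or wider than 1000 bp. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.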

Results

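STAT5 binding was mapped in leukemic B cell progenitors from a mouse with a constitutively active Stat5b transgene, after IL7 stimulation. The data consisted of 1 peak list from 1 STAT5 ChIP library, for which 1 input library was also sequenced. The series title concerns how STAT5 opposes the enhancer networks of B cells, so the questions were where STAT5 lay in the genome and whether its sites fell near B lineage genes. The list held 5908 peaks, which covered 1988.73 kb. Their widths ranged from 193 to 3660 bp, with a median of 295 bp and quartiles of 236 and 388 bp. Read depth is unknown, and a gene without a listed peak is one where none passed the unstated threshold, not one shown to be free of STAT5.

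The first peak of the deposited order lay inside Cdk5rap1 (chromosome 2, 154372517 to 154372908), 326 bp from a gene end. The second lay at Lta, which encodes lymphotoxin alpha (chromosome 17, 35205053 to 35205758), 173 bp from a gene end. The 8th lay 11423 bp from Socs1, a feedback inhibitor of JAK kinases (chromosome 16, 10772049 to 10772722). The 10th lay inside Pan2 and 10718 bp from Stat2, a transducer of interferon signals. The 13th lay inside Bcl6, a transcriptional repressor (chromosome 16, 23981067 to 23981715). The 17th lay inside Bcl2l1, which encodes the survival protein Bcl-xL (chromosome 2, 152789359 to 152789951), although the nearest gene end was that of Cox4i2. The genes nearest to the others were Fgd2, Pgf, Tbc1d16, Vash1, Gm266, Txnrd3, Zfp398, Nsd3, Psmd3, Hemk1, Sipa1l1, Camk2d, H2bc11 and Lrrc4c. The Lrrc4c peak, the 11th, was 1094 bp wide and 1035113 bp from the gene.

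STAT5 peaks were concentrated at the ends of protein-coding genes. Of 5901 peaks on assembled chromosomes, 940 (15.9%, 95% interval 15.0 to 16.9) lay within 1 kb of a gene end, where random placement put 3.17% ± 0.223 (SD of placements), a ratio of 5.03. A further 2571 peaks (43.6%, 42.3 to 44.8) lay inside a protein-coding gene, against 39.5% ± 0.651 at random, a ratio of 1.10. Intergenic sequence held 1865 peaks (31.6%, 30.4 to 32.8), against 49.1% ± 0.640 at random. Each of these 3 classes had an adjusted permutation p of 0.00266 (0.002 before adjustment, the smallest possible). The 525 peaks inside other annotated genes (8.90%, against 8.24% ± 0.357 at random) did not pass (adjusted permutation p = 0.0679), but did by any overlap of 1 bp (adjusted p = 0.0340, range over alternatives 0.0340 to 0.402). The excess inside protein-coding genes was lost when gene ends were widened to 5 kb (ratio 1.01, adjusted permutation p = 0.735, range over alternatives 0.002 to 0.735), which also lowered the ratio at gene ends to 2.44. Peaks at gene ends had a median width of 296 bp and intergenic peaks one of 299 bp.

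**Figure D1:**
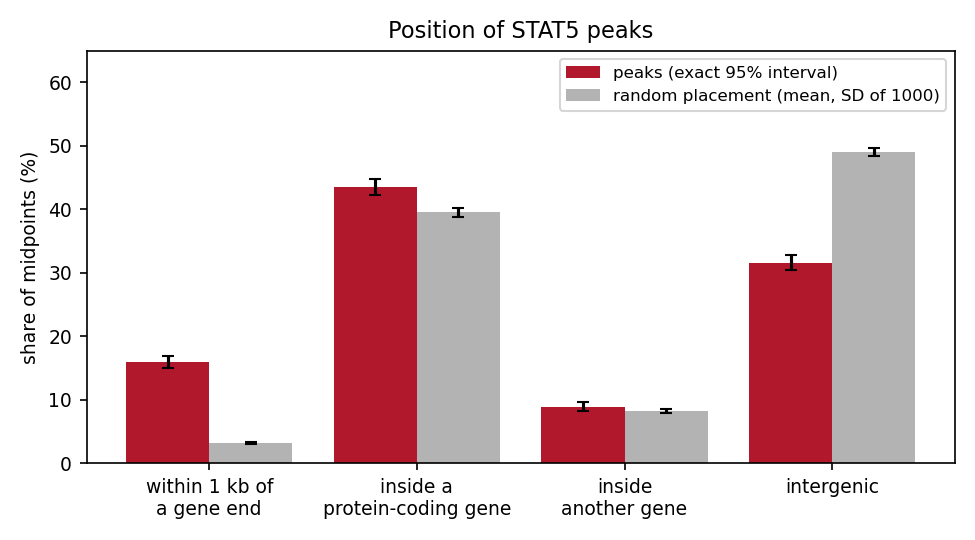
Share of peak midpoints (%, vertical axis) in 4 classes of position for the STAT5 peaks (red, with exact 95% intervals) and for random placements on the same chromosomes (grey, mean and SD of 1000 placements). Gene ends held 15.9% of the peaks against 3.17% at random, and intergenic sequence 31.6% against 49.1%.

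Chromosome X was nearly empty of STAT5 peaks. It held 44 peaks where its length gave 372.3, a ratio of 0.118 (95% interval 0.0859 to 0.159), and chromosome Y, for which length gave 201.5, held no listed peak. The density was 0.263 peaks per Mb on X and 2.44 per Mb on the autosomes, 9.30-fold higher. Among autosomes it ran from 1.58 per Mb on chromosome 14 to 3.48 per Mb on chromosome 11. The X peaks had a median width of 234.5 bp, against 295 bp on autosomes. Chromosomes differed from their lengths as a set (permutation p = 1e-04, the smallest possible), and X, Y and chromosome 14 were each below expectation with an adjusted permutation p of 0.000525. For Y this result says nothing about binding. The labels give no sex, so the cells may have lacked Y, and whether reads can be placed on Y was not checked.

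Against an expectation that included X and Y, 9 autosomes held more peaks than their length gave (chromosomes 7, 9, 10, 11, 12, 15, 16, 17 and 19). Among autosomes alone, 9, 11, 12, 16, 17 and 19 stayed above expectation, 7, 10 and 15 no longer passed, and chromosomes 1, 3, 14 and 18 were below it. Peak density rose with gene density across the 19 autosomes (Pearson's r = 0.575, permutation p = 0.00965; Spearman's rho = 0.574, permutation p = 0.0116). Without chromosomes 7 and 11, the farthest from the median gene density, r was 0.506. Chromosome 12 had the most peaks per 100 protein-coding genes, 48.4, and chromosome 7, rich in olfactory receptor genes, the fewest among autosomes, 17.8. The calls depended on the expectation: in proportion to gene number, chromosomes 10, 12, 15 and 16 were above it and 14 below, but 9, 11, 17 and 19 did not pass (adjusted permutation p from 0.0783 to 0.362). Chromosomes 1, 3, 13 and 18 were then above expectation (ratios 1.32, 1.21, 1.15 and 1.29, adjusted permutation p of 0.0007, 0.00546, 0.0491 and 0.0042). Chromosomes 2 and 7 were below it (0.866 and 0.658, adjusted permutation p of 0.00467 and 0.0007). The expectation by gene number also included X and Y, which held 44 and 0 peaks where it gave 260.9 and 69.4. This raised the ratio of every autosome, so a call near the threshold, such as that of chromosome 13, may rest on it. Gene number was not tried among autosomes alone.

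**Figure D2:**
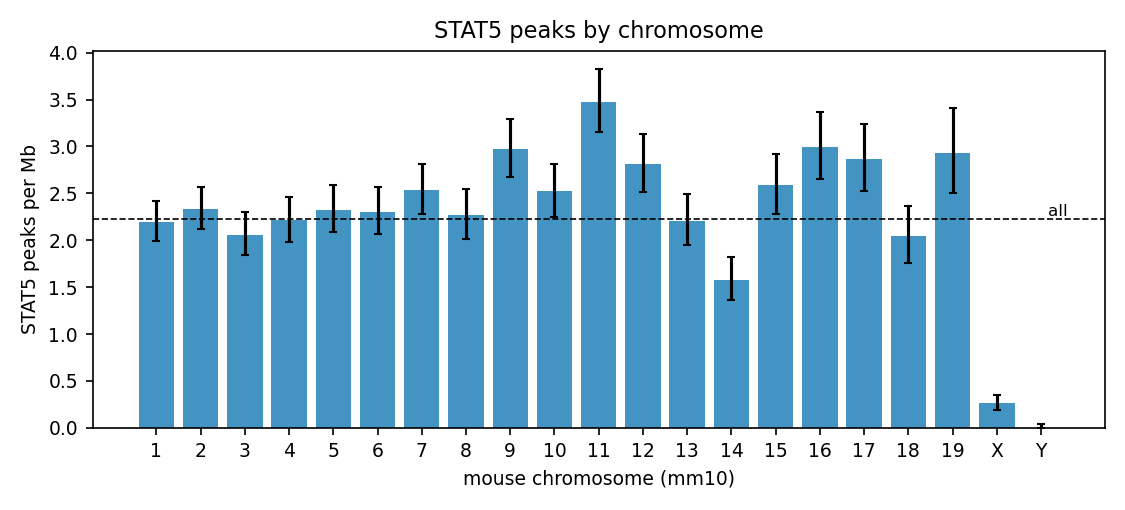
STAT5 peaks per Mb of gene span (vertical axis) for each mouse chromosome of build mm10, with exact 95% Poisson intervals that cover counting error only. The dashed line is the density over all chromosomes. Chromosome X stands at 0.263 per Mb, below each autosome, and chromosome 11 is the highest at 3.48.

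STAT5 sites lay in groups. The densest region held 10 peaks in 40.281 kb from Cish into Hemk1 (chromosome 9, 107295399 to 107335679). Cish encodes an inhibitor of cytokine receptor signalling. The next held 9 peaks in 45.445 kb around Socs3, another such inhibitor, and into Pgs1 (chromosome 11, 117946259 to 117991703). The others of the first 5, each with 8 peaks within 50 kb, lay at Cradd, which encodes a death-domain adaptor (chromosome 10, 95255350 to 95314497), Il10rb, which encodes a subunit of the IL10 receptor (chromosome 16, 91405663 to 91461352), and Il2ra, which encodes the IL2 receptor alpha chain (chromosome 2, 11620295 to 11655433).

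There were 196 regions with 4 or more peaks within 50 kb, against a mean of 1.71 and a maximum of 6 in 1000 random placements. The median distance to the nearest other peak was 30.4 kb, against 141.1 kb ± 3.0 (SD of placements), a ratio of 0.216. Both had a permutation p of 0.002, the smallest possible. The number of dense regions fell to 72 with a 20 kb window, 55 with peaks closer than 5 kb counted as 1, 46 in the first 2954 peaks and 38 in the 2931 widest peaks, each with a permutation p of 0.002.

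**Figure D3:**
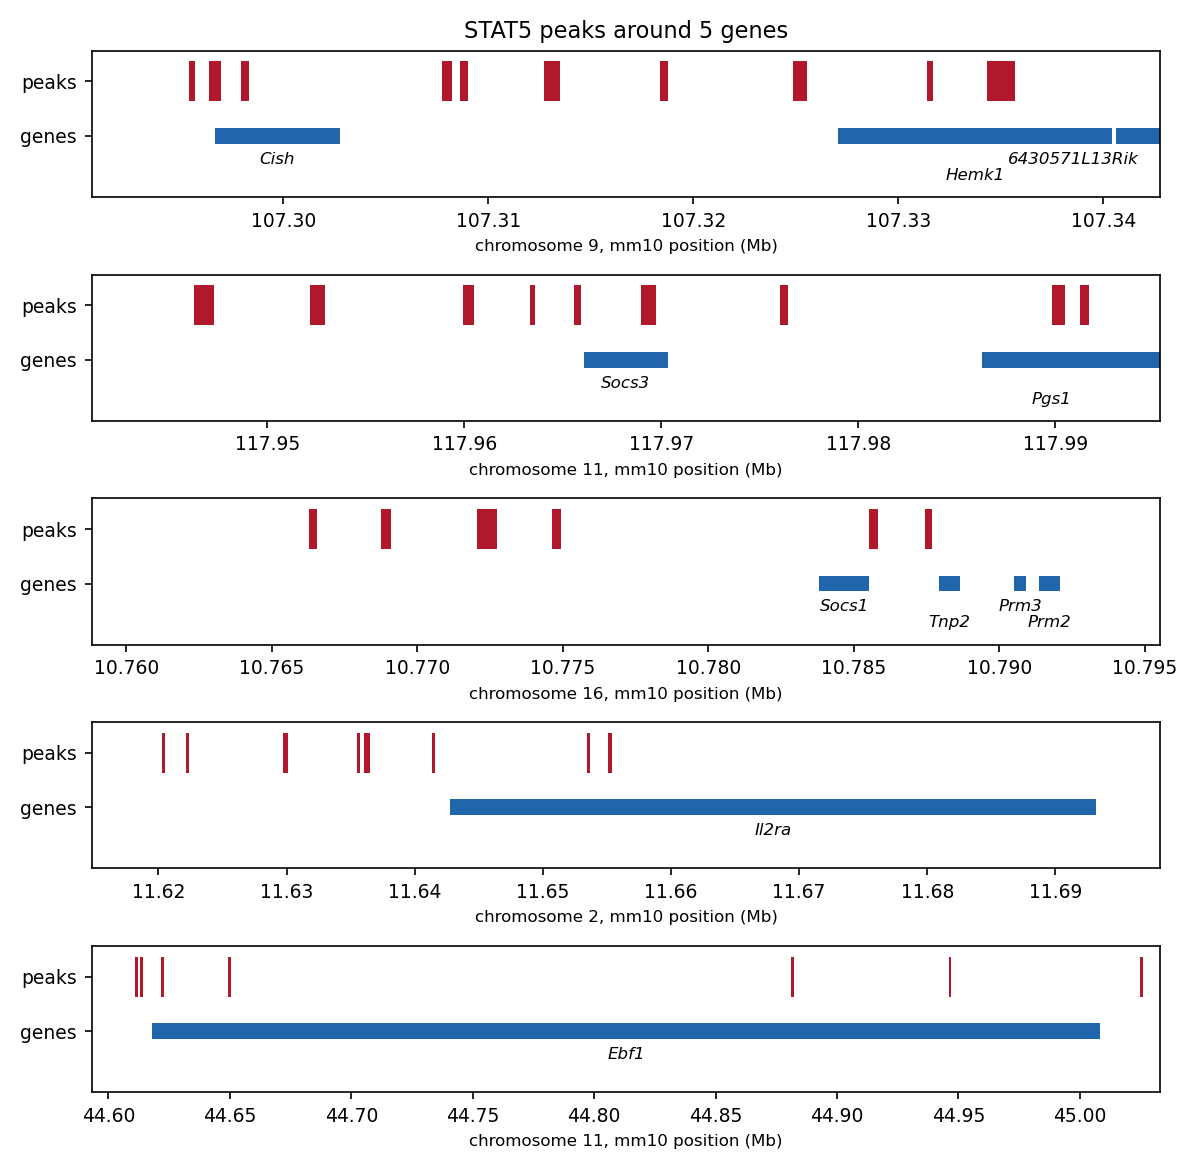
STAT5 peaks (red) and protein-coding genes (blue) around Cish, Socs3, Socs1, Il2ra and Ebf1, by position on build mm10 (Mb, horizontal axis). Narrow peaks are drawn at a minimum width to be visible. Peaks lie along the sequence from Cish into Hemk1 and on both sides of Socs3, while the 7 peaks of Ebf1 spread over and beside a much longer gene.

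Known STAT5 target genes were marked by peaks in 22 of 28 cases (78.6%, 95% interval 59.0 to 91.7), against 21.5% of genes of the same length, a ratio of 3.66. They included all 4 genes of the SOCS family in the list, negative regulators of cytokine signalling: Socs3 had 8 peaks, Cish 7, Socs1 6 and Socs2 5. The survival genes Mcl1, Bcl2 and Bcl2l1 had 7, 6 and 3 peaks, and Il2ra had 6. Bcl6 had 3 peaks, the kinase gene Pim1 4, the D-type cyclin genes Ccnd2 and Ccnd3 2 and 3, and Tnfrsf13b 2. Myc had 1, 1039 bp outside the gene. Id1, Igf1, Csn2, Gzmb, Prf1 and Dusp6 had none. The adjusted permutation p was 0.0008 (0.0002 before adjustment, the smallest possible). Of the 28 genes, 13 were also members of another list, and 9 of the other 15 had a peak.

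Genes of the JAK-STAT pathway had a peak in 21 of 34 cases (ratio 2.5, adjusted permutation p = 0.0008). Of the 34 members, 12 belong to another list, and 12 of the other 22 had a peak. Apart from the Socs genes, an early peak, place 10 in the deposited order, was counted for Stat2. That peak lay inside Pan2 and 10718 bp from Stat2, while the peak 107 bp from Stat2 had place 2673. Of the STAT5 genes themselves, Stat5b had 1 peak, place 5802 in the deposited order, and Stat5a none. Il7r, which encodes the IL7 receptor alpha chain, had 3 peaks, the earliest 202 bp from a gene end.

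Transcription factor genes of the B lineage had the highest share of all 20 lists: 23 of 24 had a peak (95.8%, 95% interval 78.9 to 99.9), against 28.7% of genes of the same length, a ratio of 3.34 (adjusted permutation p = 0.0008). Ets1 had 9 peaks, Runx1 and Tcf4 8 each, and Ebf1 and Fli1 7 each. Ikzf3 had 4, Irf4 and Ikzf1 3 each. Pax5, which maintains B cell identity, had 2 peaks, 1 of them inside the gene (chromosome 4, 44680281 to 44680504). Sox4 was the member without a listed peak.

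Genes of pre-B cell receptor and B cell receptor signalling had a peak in 23 of 28 cases (82.1%, 63.1 to 93.9; ratio 3.29, adjusted permutation p = 0.0008). Fyn had 6 peaks, Pik3cd 5 and Syk 4. Blnk, the gene mutated in this mouse, had 3, and Vpreb2, a component of the surrogate light chain, 3. Rasgrp3 had 1 peak. Cd72, Prkcb, Ptpn6, Malt1 and Cblb had none. B cell surface genes had a peak in 17 of 26 cases (ratio 2.94, adjusted permutation p = 0.0008), among them Bst1 with 4, Cd74 and Ccr7 with 2 each and Cxcr4 with 1.

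Chromatin regulator genes also passed, with 16 of 24 (ratio 2.35, adjusted permutation p = 0.002). Arid1b had 11 peaks, Smarca4 3, Arid1a 2 and Dnmt3b 1. The NF-kB family and its regulators passed with 12 of 24 (ratio 2.09, adjusted permutation p = 0.0255): Nfkb1 had 3 peaks, Bcl3 2, and Tnip1 and Traf6 1 each, while Rel, Rela and Relb had none. Genes of leukemia suppression and transformation passed with 17 of 32 (ratio 1.86, adjusted permutation p = 0.02), but 16 of these 32 belong to another list and 5 of the other 16 had a peak. Runx1, Erg and Etv6 had 8, 4 and 3 peaks.

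The calls of these 3 lists depended on the setting. In the 2931 widest peaks the adjusted permutation p was 0.0532 for each. In the first 2954 peaks the adjusted permutation p was 0.0775 for the NF-kB list and 0.329 for the leukemia list, which also lost its call with flanks of 50 kb (adjusted p = 0.0800). Over the 10 alternatives it ranged from 0.000667 to 0.0532 for chromatin, 0.00114 to 0.0775 for NF-kB and 0.00171 to 0.329 for leukemia.

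**Figure D4:**
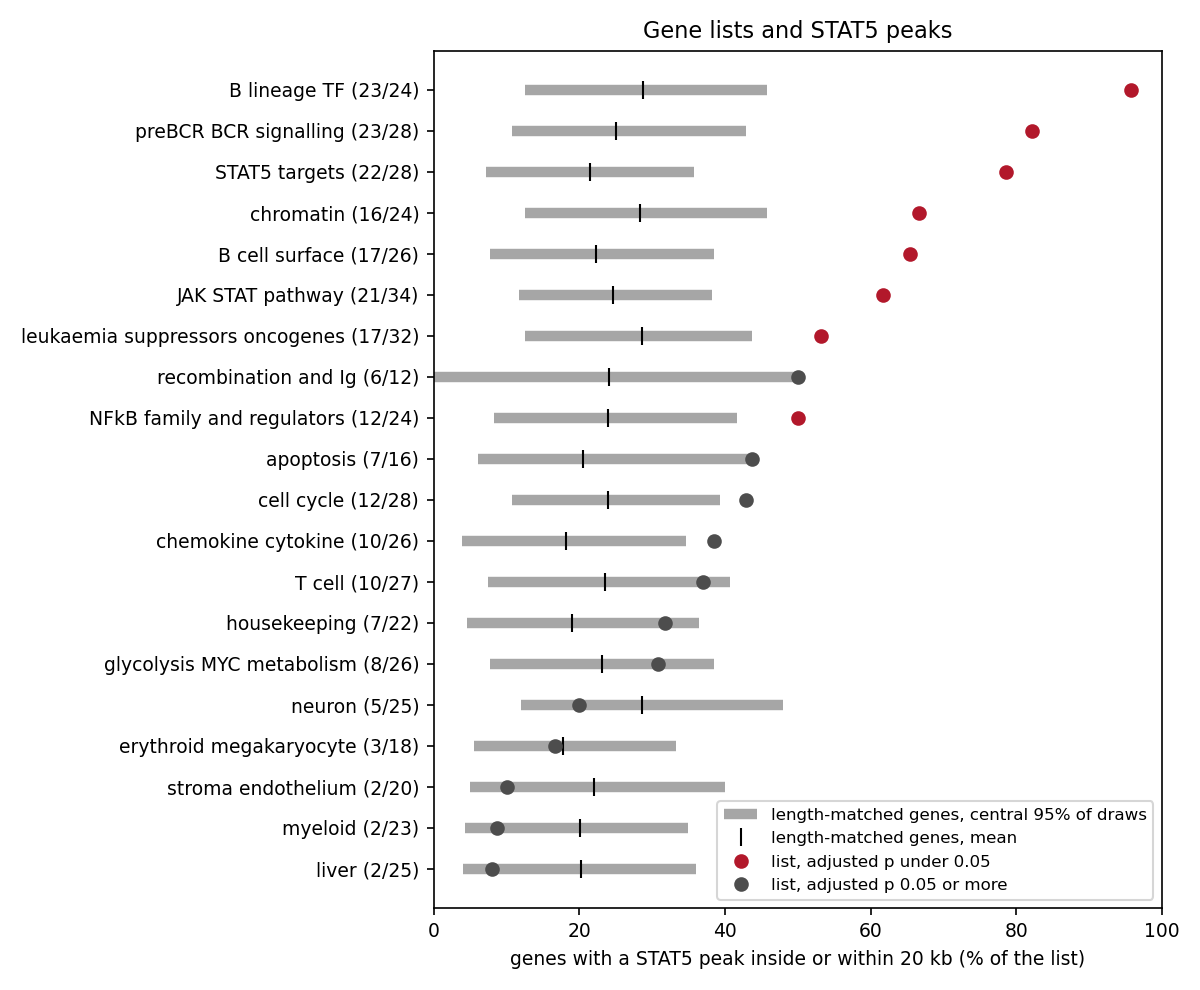
Share of genes with a STAT5 peak inside or within 20 kb (%, horizontal axis) for 20 gene lists (points, with genes with a peak over members) and for genes matched on length (black ticks, mean; grey bars, central 95% of 10000 draws). The 8 lists in red had an adjusted permutation p under 0.05, led by B lineage transcription factors at 95.8%.

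The other 12 lists did not pass. Among lymphoid and growth genes, 10 of 26 chemokine and cytokine genes had a peak (ratio 2.12, adjusted permutation p = 0.0564), with 4 at Lta, 3 at Tnf and 2 each at Ltb and Tgfb1, the first 3 of which are neighbours that share peaks. This list passed in 5 of 10 alternatives, with a ratio of 3.95 at 5 kb (adjusted permutation p = 0.002) and 4.40 by the nearest gene end (0.000667, range over alternatives 0.000667 to 0.132). Cell cycle genes had a peak in 12 of 28 cases (ratio 1.80, adjusted permutation p = 0.0852), among them Rbl1 with 2 peaks and Cdkn1a with 1. Apoptosis genes had one in 7 of 16 (ratio 2.14, adjusted permutation p = 0.111), including Bax with 1. Recombination genes had one in 6 of 12 (ratio 2.08, adjusted permutation p = 0.151): Poll had 3 peaks, Rag2 2, and Rag1, Polm and Xrcc6 1 each. The peak of Rag1, place 5562 in the deposited order, was also counted for Rag2.

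T cell genes had a peak in 10 of 27 cases (ratio 1.58, adjusted permutation p = 0.232), with 4 at Cd2, 2 at Thy1 and 1 at Lck. Of the other cell types, 2 of 23 myeloid genes had a peak (Itgam and Adgre1; ratio 0.432), 3 of 18 erythroid and megakaryocyte genes (Hbb-bt and Tfrc among them; 0.936), 2 of 20 stromal and endothelial genes (Pecam1 and Tek; 0.455), 5 of 25 neuronal genes (Gria2, Slc17a7, Syn1 and Camk2a among them; 0.698) and 2 of 25 liver genes (Cyp8b1 among them; 0.395). Their adjusted permutation p-values ran from 0.263 to 1. Housekeeping genes had a peak in 7 of 22 cases (ratio 1.68, adjusted permutation p = 0.283), among them Rpl13a, Hsp90ab1 and Tubb5. Genes of glycolysis and MYC-driven metabolism had one in 8 of 26 (ratio 1.33, adjusted permutation p = 0.503), among them Rptor, Slc2a1, Eno1 and Odc1. With flanks of 50 kb, housekeeping genes passed (ratio 2.29, adjusted permutation p = 0.0016, range over alternatives 0.0016 to 0.805).

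Lists were then compared with each other directly, in 12 pairs chosen after the counts were seen. B lineage transcription factor genes had a peak more often than T cell genes (odds ratio 39.1, adjusted Fisher's exact p = 3.11e-05), housekeeping genes (49.3, 2.97e-05) and NF-kB genes (23, 0.0014). Receptor signalling genes and STAT5 targets also exceeded T cell genes (odds ratios 7.82 and 6.23, adjusted Fisher's exact p of 0.00156 and 0.00348). B cell surface genes did not (odds ratio 3.21, adjusted Fisher's exact p = 0.0556). These odds ratios are not matched on gene length.

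STAT5 target genes and B lineage transcription factor genes were each served by 79 distinct peaks, from 22 and 23 genes. The comparisons of these peaks count each peak as independent, although many share a gene, so their p-values are too small. They were also not adjusted. The peaks of the targets were wider, with a median of 349 bp against 301 bp (permutation p = 0.00818). Of the target peaks, 52 (65.8%) stood among the first 2954 of the deposited order, against 39 (49.4%) of the others, which did not pass (Fisher's exact p = 0.0530).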

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

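The tests of chromosome X and the comparison of B lineage genes with housekeeping and ribosomal protein genes were chosen only after the result was seen. The joining of neighbouring peaks was chosen after the data were examined but before its value was known. Placement that keeps the class of each peak and matching on length and neighbours were planned, but what they should show under each explanation was written after their values were seen.

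The list held 7 peaks on sequences outside the assembled chromosomes, which no comparison of the report used. Of these, 4 lay on JH584304, and GL456216, GL456233 and GL456389 held 1 each.

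Chromosome X held few STAT5 peaks, and the tests argued against 2 technical explanations, the second under an assumption that was not checked. Fewer or shorter genes on X were tested by setting its genes beside autosomal genes of the same length: 50 of 963 X genes had a peak against a mean of 217.3, a ratio of 0.230, and the lowest of 10000 draws gave 170. Repeated sequence that reads cannot be placed in was tested at the ends of named genes. These were assumed to be mostly unique, which could not be checked without the genome sequence. Of 799 named X genes, 10 had a peak within 1 kb of an end, 0.241 of the matched mean and below the lowest draw, 16. A single copy of X in the cells may lower the signal and stays open: 27.3% of the X peaks (95% interval 15.0 to 42.8) stood in the first 2954 places, but the key of that order is unknown, so this share does not measure signal; the test also asked for more than 3 peaks on Y, where 0 were listed against 201.5 by length, and the labels give no sex. No biological explanation was tested, and filtering of X before deposition stays open too.

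The dense regions may in principle be broad sites split by the peak caller. With peaks closer than 5 kb counted as 1, 55 regions remained, against at most 6 in random placements, which argues against splitting as the whole cause; how much of the fall from 196 came from split sites was not tested, since joining lowers the count in any case. Grouping of genes was tested by placements that kept the class of each peak, of which the highest gave 9 regions, so the classes do not account for 196 either. Shared open chromatin of these cells stays open, as no accessibility or expression data were used here, and no biological explanation was tested.

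The peaks near B lineage transcription factor genes could reflect active genes in general or long genes. Given gene length, the odds ratio at 20 kb was 30.0 against housekeeping genes and 21.1 against ribosomal protein genes (adjusted exact conditional p of 0.000147 and 0.000118). Median lengths were far apart: 90.7 kb for B lineage factors, 5.68 kb for housekeeping and 3.16 kb for ribosomal protein genes. The test took the odds over matched genes to be comparable across these lengths, which was not checked. At 50 kb all 24 B lineage genes had a peak, against 16 of 22 housekeeping and 36 of 81 ribosomal protein genes (adjusted exact conditional p of 0.0221 and 3.46e-05). This argues against active transcription as the whole cause only if the housekeeping and ribosomal protein genes were active in these cells. The same reading needs odds that can be compared across such lengths. Expression was not measured here. A part played by active transcription stays open in any case. Ribosomal protein genes at 20 kb (ratio 2.31) and housekeeping genes at 50 kb (2.29, against 2.67 for B lineage factors) also exceeded genes of their length. Against genes matched on length and number of neighbours the ratio was 3.43, which argues against length as the whole cause. Chromatin open in B cell progenitors whatever STAT5 does remains a candidate explanation, untested here. Beyond active genes, no biological explanation was tested.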

How the results depend on the processing

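The settings by width, deposited order, gene ends, doubtful peaks, named genes, gene number and autosomes were chosen after the data were examined. Of 256 values under alternatives, 123 for the questions asked and 104 for lists that did not pass kept their direction and their side of the threshold (counts within 1.5 times). X stayed between 0.0595 and 0.169 of expectation, and 5 lists passed in each of 10 alternatives: STAT5 targets (ratio 2.36 to 6.20), B lineage factors (2.67 to 4.43), receptor signalling (2.66 to 3.79), B cell surface (1.94 to 3.96) and JAK-STAT (1.93 to 3.43). The number of lists that passed ranged from 6 to 10.

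In the 2931 widest peaks the dense regions numbered 38, and NF-kB, leukemia and chromatin genes had ratios of 2.43, 2.02 and 2.23 and did not pass; erythroid and neuronal genes moved to 1.10 and 1.21, neither passing. In the first 2954 peaks the dense regions numbered 46, NF-kB (2.31) and leukemia genes (1.66) did not pass and erythroid genes moved to 1.09. Fewer peaks enter both settings. With flanks of 50 kb, leukemia genes (1.48) did not pass and myeloid (1.04) and erythroid (1.15) genes moved above 1. With 5 kb, housekeeping genes moved to 0.461. A 20 kb window gave 72 dense regions and joining peaks within 5 kb gave 55, as fewer peaks can meet either rule. Gene ends of 5 kb left a ratio of 1.01 inside protein-coding genes, and overlap of 1 bp took other annotated genes past the threshold at 1.09. The cause was not tested for the lists or the classes. Chemokine and cytokine genes, which did not pass, did so in 5 of 10 alternatives (adjusted p 0.000667 to 0.132), cell cycle genes in 2 (0.0400 to 0.588), and apoptosis (0.0487 to 0.625) and stromal genes (0.0492 to 0.976, below matched genes) in 1 each.

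The settings planned with motifs, GC-matched windows, a score threshold or transcription starts were not run, since sequence, strand and scores were not used here. No paired analysis was possible because there was 1 ChIP library. With unknown depth, absence of a peak limits nothing about weak binding.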

Other observations

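The gene families and loci below were chosen after their values were seen, from a view of peak shares by gene symbol, so their p-values are not independent evidence. Of 17 families set beside genes of the same length, interleukin and interleukin receptor genes had a peak in 32 of 83 cases (ratio 1.74, adjusted permutation p = 0.0034) and ribosomal protein genes in 28 of 81 (2.31, 0.00068). The SOCS family had 5 of 8 (2.99, adjusted permutation p = 0.0422). All 8 Gimap genes, GTPases of lymphocytes, had a peak within 20 kb, but they lie in 1 cluster and share peaks. Other families had few: 12 of 1109 olfactory receptor genes (0.259) and 1 of 352 vomeronasal receptor genes (0.0273). The matched genes could include members of the same family, and matching among named genes only gave 0.121 and 0.0201. No peak was listed for 109 keratin and keratin-associated genes, 42 beta-defensin genes, 39 Hox genes or 24 C-C chemokine genes. The adjusted permutation p was 0.0422 for the C-C chemokines and from 0.00068 to 0.00637 for the others. The draws treat genes as independent, so p-values are too small for any family whose members are neighbours. Histone genes (14 of 59), ETS factors (11 of 26), cyclin-dependent kinases (9 of 19), solute carriers (80 of 378), zinc finger proteins (88 of 397), MAPK phosphatases (6 of 24) and mitochondrial ribosomal proteins (12 of 78) did not pass. The definitions of the ribosomal, solute carrier and cyclin-dependent kinase families were changed once after their values were seen, to remove unrelated genes with similar symbols and, for solute carriers, also to add the Slco genes (375 genes at first, 378 after). This ended the call of the cyclin-dependent kinases, which as first defined had a peak in 13 of 26 cases (ratio 2.12, adjusted permutation p = 0.0113) and after it in 9 of 19 (1.92, 0.068). Ribosomal protein genes passed under both definitions (31 of 97 at first, ratio 1.94) and solute carriers under neither.

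Antigen receptor loci also held STAT5 peaks. Since peaks lie in groups and the loci were picked after the fact, their counts are given beside those expected from length without a test. The T cell receptor gamma locus (chromosome 13, 19178042 to 19352343) held 3 peaks where its length gave 0.385. These lay near the V and C segments, the earliest between Trgv7 and Trgv4 (19182260 to 19182809). The immunoglobulin kappa locus held 14 against 7.31, the heavy chain locus 12 against 7.73, and the lambda, T cell receptor alpha/delta and beta loci 1, 5 and 3 against 0.597, 2.84 and 1.54. A kappa peak lay between Igkj5 and Igkc (chromosome 6, 70725721 to 70726064), 1798 and 371 bp from them. A heavy chain peak lay between Ighm and Ighj4 (chromosome 12, 113427329 to 113427615), 4599 and 899 bp from them.

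Genes with the most peaks inside or within 20 kb were Foxp1 with 13, then Arid1b, Cradd and Cyth1 with 11 each; counts were not matched on gene length. Among the few noncoding genes examined, Pvt1 had 3 peaks, Mir21a 2, and Mir155hg, Mir155, Mir142, Mir17hg and Malat1 1 each. Neat1 and Mir181a-2 had none.

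Some peaks lay in places, picked after their widths were seen, that look like repeated sequence. The widest, 3660 bp, was 1 of 2 over the ribosomal RNA pseudogene Rn18s-rs5 (chromosome 17, 39843036 to 39848733). Another 7, of 193 to 570 bp, lay at the start of chromosome 9 (3000296 to 3030220), 5 of 1023 to 2184 bp beside Atad2b (chromosome 12, 5049832 to 5061534) and 3 of 302 to 1094 bp at 98662247 to 98667332 of chromosome 2, including the 11th of the deposited order.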
